A study of Mus musculus with 9 samples.

How the data were processed

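RNA was measured in 9 mouse placentas collected at gestational day 19, 4 from control mothers and 5 from mothers dosed with airborne particulate material (AP). Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a strand-preserving kit that depletes ribosomal RNA, then sequenced on an Illumina HiSeq instrument. The labels also name the molecule polyA RNA, which does not match depletion of ribosomal RNA, and which applies was not settled. Groups and replicate numbers came from the sample titles.

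The deposited count table holds whole-number read counts per gene symbol, not normalized, as the authors made it. Per the submitters' processing notes, FastQC, STAR, featureCounts, Subread and DESeq2 were used with the mouse build mm10, without versions or roles; the annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. Close gene copies and overlapping or antisense genes are therefore uncertain. A second deposited table holds the authors' comparison of AP with control. Per the file headers it gives a mean normalized signal per gene, a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value, and the authors' call as a score of 1, 0 or −1. The calls coincide with an adjusted p-value below 0.05 and an absolute log2 fold change over 1, as tested on the table. Values of that table are printed as the authors' own.

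The depth ran from 15448080 to 26552149 counts per library. A biological coefficient of variation of 24.3% set the precision of most genes. Of 24421 symbols, 23376 matched GENCODE M21 (GRCm38, the same assembly as mm10), which gave the coordinates; of the tested symbols 14053 matched. No replicate pair within a group agreed within sampling noise (chi-square per degree of freedom of at least 30.4), so each library counted as 1 sample. This check cannot tell whether placentas shared a litter.

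Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 14573, and scaled with TMM factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with the group as the only term, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled and are given as mean ± SD over libraries. The 41 fixed lists were 24 pathway lists, 16 lists of cell type markers and 1 of sex chromosome genes. Lists with at least 5 tested members were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and with fry, which tests the list's own genes without comparing them with others. A list score per library is the mean centred log2(CPM + 1) of its members. Differences in scores and library measures were tested by exact permutation over all 126 splits of 9 libraries into 4 and 5, 2-sided.

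Genes were named by a rule set before the data were examined. It took the 10 largest changes in each direction among called genes with a mean CPM of at least 1, no overlap between the groups and no predicted name. From each list it took up to 4 called members or, where none passed, up to 2 with the smallest p. It also took 11 transporter, methylation and xenobiotic genes whatever their values. Genes outside it are said to have been singled out after their values were seen.

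The tests were run on simulated data for the AP against control comparison, with counts drawn from the real means, dispersions and library sizes and 200 changed genes. Another 20 genes were shifted by 0.5 on the log2 scale, and calls among them count as neither recovered nor false. Over 14455 genes, edgeR recovered 72% of 100 genes changed by 1 on the log2 scale and 92% of 100 changed by 2, with 9 false calls among 174. DESeq2 (1.42.0) ran on 14567 genes, recovered 78% and 94%, and made 40 false calls among 222. On 14455 genes limma voom recovered 69% and 91% with 8 false calls among 169. Alternatives set beforehand were other scaling factors, other count filters, DESeq2, limma voom, robust dispersions and the replicate number as a block. Also set beforehand were 1 surrogate variable (sva 3.50.0), removal of the sex chromosome list and each library left out in turn. Only Xist of that list was tested, so its removal is no check on the sex of the fetus. Alternatives added after seeing the data left out pairs of libraries, thinned the counts to 1 depth, removed Rn45s or added yolk sac and decidua scores as covariates. Other measurements the study describes, on the mothers, the fetuses and hydroxymethylation, were not analysed here.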

Results

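Bulk RNA sequencing was used to ask how gene expression in the mouse placenta changed after the mother had been given an air pollutant during pregnancy. The pollutant (AP) was a reference airborne particulate material suspended in buffer at 15 µg/µl, and pregnant C57/BL6 mice received 300 µg/day into the nose. Placentas were collected at gestational day 19. The count table held 4 control libraries and 5 AP libraries and listed 24421 gene symbols, of which 3854 had no count in any library. The 4 control libraries held 18735485, 15619521, 15448080 and 18225882 counts. The 5 AP libraries held 24881655, 20302131, 23864365, 26552149 and 26020252 counts, so every AP library was deeper than every control (17007242 ± 1715480 against 24324100 ± 2476870 counts, mean ± SD, n = 4 and 5, exact permutation test, 2-sided p = 0.0159). Rn45s, the precursor of ribosomal RNA, took 8.69 ± 5.07% of the counts in control and 4.53 ± 1.07% in AP libraries (exact permutation test, 2-sided p = 0.0635, n = 4 and 5), with 15.5% in control replicate 3 as the highest share. The labels do not say whether placentas of a group came from separate litters. All p-values here treat each placenta as independent and may be too small if some shared a mother, since the mothers were dosed.

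AP placentas had lower levels of a set of immediate early genes, which cells transcribe within minutes of a stimulus. Fosb was 4.86-fold lower, Nr4a1 3.64-fold lower, Egr1 3.56-fold lower, Dusp1 2.87-fold lower and Fos 2.75-fold lower than in control placentas. Fewer genes were higher, led by the tight junction gene Cldn1 (3.17-fold), the imprinted gene Magel2 (2.69-fold) and Cyp11a1, the enzyme that starts steroid hormone synthesis from cholesterol. Of 14573 genes tested with edgeR's quasi-likelihood test, 50 passed a Benjamini-Hochberg adjusted p of 0.05, 14 higher and 36 lower in AP, and 10 of them changed by more than 2-fold. In all 50 the AP and control libraries did not overlap. Such separation was seen in 819 tested genes, and chance alone gives it to 1.59% of genes. The number of calls fell whenever 1 library was left out. It was 17, 31, 15 and 28 without control replicates 1, 2, 3 and 4, and 17, 13, 32, 30 and 10 without AP replicates 1, 2, 3, 4 and 5.

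**Figure D1:**
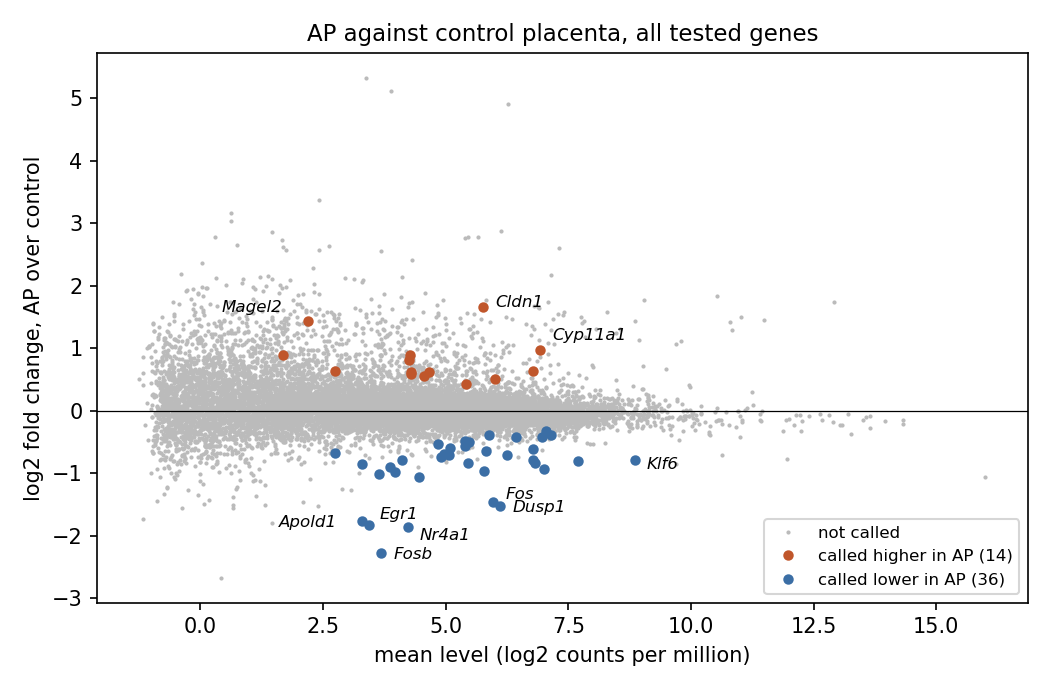
Log2 fold change of AP over control against mean level in log2 CPM (counts scaled to the effective library size) for all 14573 tested genes. Orange points are the 14 genes called higher, blue points the 36 genes called lower and grey points the genes that did not pass, and Fosb is the lowest called gene at −2.28.

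Immediate early genes formed the clearest group among the lower genes. Of 20 tested members of this list, 9 fell, none rose and 11 did not pass. Adjusted over the list alone, 16 fell. Dusp1, a phosphatase that switches off MAP kinases, fell from 108 ± 15.1 to 37.6 ± 2.77 CPM (log2 fold change −1.52 ± 0.10 SE, edgeR adjusted p = 0.000524). Egr1, a zinc finger transcription factor, fell from 18.1 ± 3.23 to 5.09 ± 0.833 CPM (−1.83 ± 0.16, adjusted p = 0.00178). Jun and Fos, partners in the AP-1 transcription factor, had log2 fold changes of −0.93 ± 0.08 and −1.46 ± 0.18, and Fosb one of −2.28 ± 0.27. The nuclear receptor gene Nr4a1 changed by −1.86 ± 0.18. Klf6, the most abundant of these genes, went from 603 ± 33.3 to 350 ± 12.5 CPM. The list as a whole was lower by camera, a test against all other genes (mean log2 fold change −0.83, median −0.68, adjusted p = 3.86e-26). It was the only list whose call held with an estimated correlation between its genes (adjusted p = 0.0289). Its score, the mean centred log2(CPM + 1) of the members, was 0.43 ± 0.08 in control and −0.34 ± 0.12 in AP libraries (SD, n = 4 and 5, exact permutation test, 2-sided p = 0.00794, the smallest that 126 splits of the libraries allow). Adjusted over the lists scored, this exact permutation p became 0.106. Fosb lies on chromosome 7 from 19302696 to 19310051, Egr1 on chromosome 18 from 34859823 to 34864984, Fos on chromosome 12 from 85473890 to 85477273 and Nr4a1 on chromosome 15 from 101254269 to 101274795. All are protein-coding genes in GENCODE M21 (GRCm38, the assembly called mm10), and counts cover the whole gene.

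**Figure D2:**
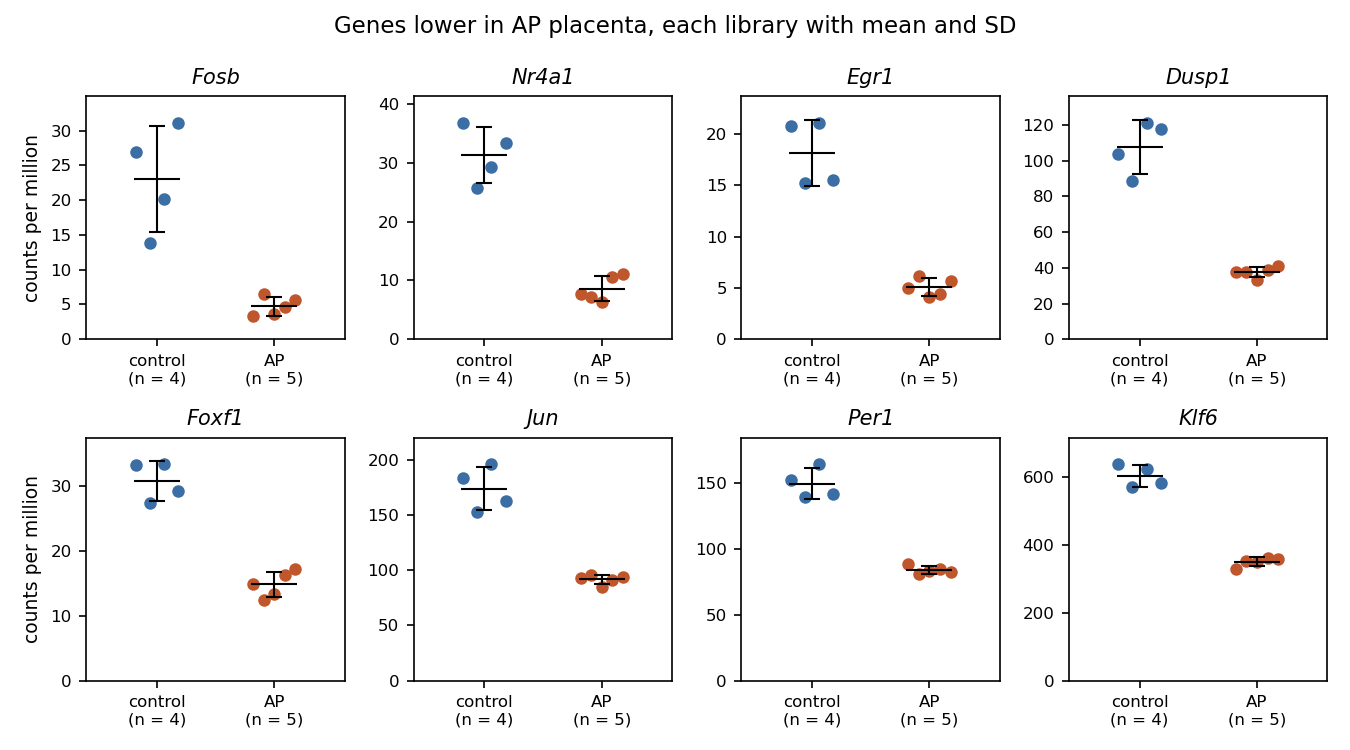
CPM of 8 genes lower in AP placenta, on axes that start at 0. Each point is 1 library (blue, 4 controls; orange, 5 AP), the wide bar is the group mean and the error bar the SD; in each panel all AP points lie below all control points.

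Other lower genes with large changes were the endothelial gene Apold1 (−1.76 ± 0.28), the forkhead transcription factor gene Foxf1 (−1.05 ± 0.11), Cdk5r1, an activator of the kinase CDK5 (−1.01 ± 0.13), Spry4, an inhibitor of receptor tyrosine kinase signalling (−0.98 ± 0.12), and the kinase gene Plk3 (−0.96 ± 0.12). The clock gene Per1 fell from 150 ± 11.5 to 83.9 ± 2.83 CPM (−0.84 ± 0.07, edgeR adjusted p = 0.00132). It was the only member of 16 tested in the circadian clock list to pass with edgeR or DESeq2, and the list was not called by camera (adjusted p = 0.344). Igfbp3, which binds insulin-like growth factors, fell from 136 ± 18.8 to 89.1 ± 6.42 CPM (−0.61 ± 0.10, adjusted p = 0.0414) and was edgeR's only call among 25 genes of insulin, IGF and leptin signalling, of which DESeq2 called 1 higher and 1 lower. Fosb, Nr4a1, Egr1, Dusp1, Foxf1, Jun, Klf6 and Per1 passed in all 9 fits that left out 1 library. Cdk5r1 passed in 7 of these 9 fits, Fos and Spry4 in 6, Plk3 in 5, Apold1 in 2, and Igfbp3 in 1 (without control replicate 1).

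Among the higher genes, Cldn1 rose from 24.6 ± 10.2 to 78.1 ± 19.1 CPM (log2 fold change 1.67 ± 0.27 SE, edgeR adjusted p = 0.0414). Magel2, a paternally expressed gene at a low level, rose from 2.27 ± 0.58 to 6.11 ± 0.78 CPM (1.43 ± 0.19, adjusted p = 0.0175) and was edgeR's only call among 34 imprinted genes, of which DESeq2 called 1 higher and 2 lower. Cyp11a1 rose from 79.4 ± 8.23 to 156 ± 27.2 CPM (0.97 ± 0.14, adjusted p = 0.0203) and was the only call among 18 steroid hormone genes with edgeR and with DESeq2. Tchh (0.90), the zinc finger gene Zfp420 (0.89), Npdc1 (0.81), Mtrf1l (0.63), Rsrp1 (0.63), Fam63b (0.63) and the interferon regulatory factor gene Irf1 (0.62) also rose on the log2 scale. None of these 10 calls held in every fit that left out 1 library, and each such fit has fewer samples. Magel2, Tchh and Npdc1 passed in 4 of the 9 fits that left out 1 library. Cyp11a1 passed in 2 (without AP replicate 3 or 4), Cldn1 in 1 (without control replicate 2), Rsrp1, Fam63b and Irf1 in 1 each, and Zfp420 and Mtrf1l in 0. Their direction was the same in every such fit, which is no check, because the groups did not overlap in these genes. Cldn1 lies on chromosome 16 from 26356642 to 26371841, Magel2 on chromosome 7 from 62377010 to 62381640 and Cyp11a1 on chromosome 9 from 58006411 to 58027023.

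Of 41 gene lists fixed before the data were examined, 38 had at least 5 tested members, and camera with a preset correlation of 0.01 called 7, 4 higher and 3 lower. Genes of the NRF2 oxidative stress response were higher as a group (19 of 23 with a positive log2 fold change, mean 0.25, adjusted p = 0.0101), though no member passed edgeR's test over all genes and 3 passed adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.262). Catalase (Cat) had a log2 fold change of 0.68 (edgeR adjusted p = 0.0528) and the secreted glutathione peroxidase Gpx3 one of 1.42 (adjusted p = 0.105). DESeq2 called 3 members higher, among them Cat (adjusted p = 0.000134) and Gpx3 (8.35e-05), and Gpx3 is a marked call in the authors' deposited table. The score of this list did not overlap between the groups, at −0.12 ± 0.05 in control and 0.10 ± 0.08 in AP libraries (SD, n = 4 and 5, exact permutation test, 2-sided p = 0.00794; 0.106 adjusted over the lists scored). Cytosolic ribosomal protein genes were higher by a mean of 0.11 over 35 genes (adjusted p = 0.0138; adjusted p = 0.999 with an estimated correlation), with no member passing either way of adjusting. Rps11, the member with the smallest p, had a log2 fold change of 0.26 (adjusted p = 0.231). Replication-dependent histone genes were lower by a mean of −0.51 (adjusted p = 0.0101; adjusted p = 0.241 with an estimated correlation). The list held 33 symbols, some of them older and newer names of the same gene, and 19 were in the count table. Only 5 could be tested, and 1 of these, H1f0 (−0.23, edgeR adjusted p = 0.336), is a replacement linker histone that the fixed list held though it is not of this class. No member passed edgeR's test over all genes and Hist1h1c passed adjusted over the list alone (−0.67, edgeR adjusted p = 0.0542). Hist1h1c passed over all genes with DESeq2 (adjusted p = 0.000135).

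**Figure D3:**
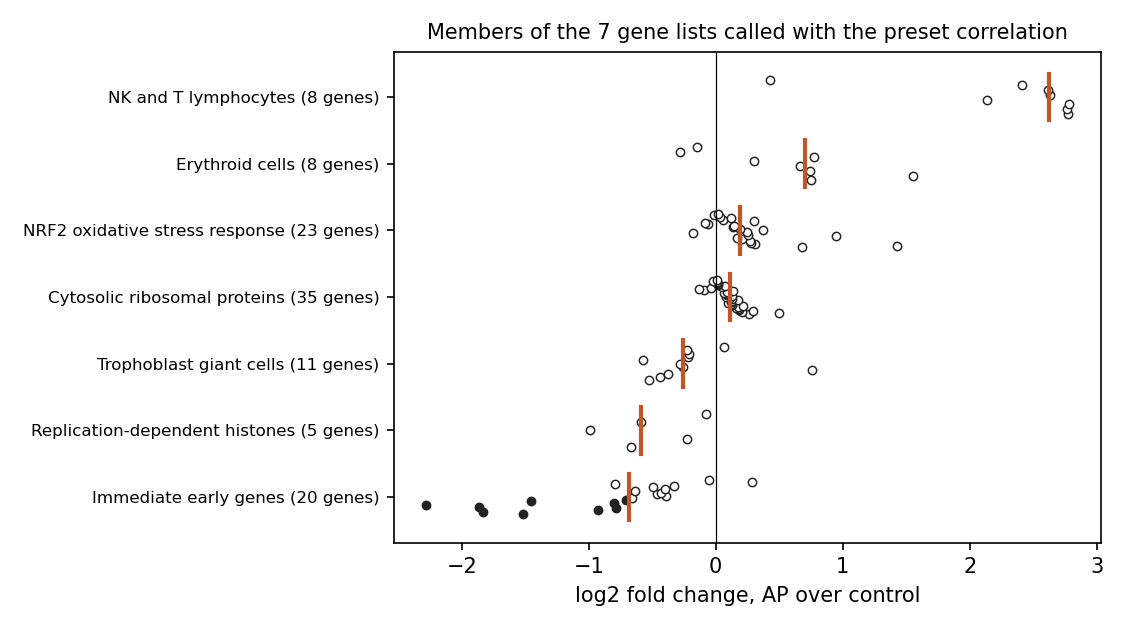
Log2 fold change of AP over control for each tested member of the 7 gene lists called by camera with the preset correlation. Each circle is 1 gene, filled where it passed over all genes, and the orange bar is the list median; only immediate early genes have filled circles, 9 of 20.

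Markers of several cell types that a placental sample can hold were also called by camera, with no member passing edgeR's test over all genes. DESeq2 called Hand1 (adjusted p = 0.0153), Slc4a1 (0.0020) and Gypa (0.000206). Trophoblast giant cell markers were lower by a mean of −0.21 over 11 genes (adjusted p = 0.0225; adjusted p = 0.655 with an estimated correlation), and 1 passed adjusted over the list alone, the transcription factor gene Hand1 (−0.53, edgeR adjusted p = 0.154). Prl2c2, which has near-identical copies, had a value of −0.44. Markers of NK and T lymphocytes were higher by a mean of 2.32 over 8 genes (adjusted p = 0.0138; adjusted p = 0.999 with an estimated correlation), and 7 passed adjusted over the list alone. The mean was 0.77 and the call was lost with the yolk sac and decidua scores as covariates, and it was 1.30 without AP replicate 2. The scores of lymphocyte and decidual stroma markers were 2.78 and 0.99 in AP replicate 2, 0.97 and 0.78 in AP replicate 5, −1.15 and −1.23 in AP replicate 4 and −1.61 and −1.01 in control replicate 4. This list was mostly granzymes of uterine NK cells, and AP replicate 2 was highest for Gzmf (263 CPM) and Gzmd (219 CPM). The granzyme genes are close copies, so reads shared between them are uncertain. Erythroid markers were higher by a mean of 0.54 over 8 genes (adjusted p = 0.0225; adjusted p = 0.655 with an estimated correlation), and 3 passed adjusted over the list alone. Slc4a1 had a log2 fold change of 0.75 (edgeR adjusted p = 0.0959) and Gypa one of 1.55 (adjusted p = 0.100). The adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in all 9 libraries. How reads matching several genes were counted is not stated in the sources used here, so these zeros are values of the table and set no limit on expression. The lymphocyte and erythroid calls were lost without control replicate 4, the giant cell call without control replicate 1 (mean −0.14, adjusted p = 0.116) or 2 (−0.19, adjusted p = 0.0569), and the ribosomal call without control replicate 1 (0.087, adjusted p = 0.0991) or AP replicate 2 (0.049, adjusted p = 0.302). Both calls were also lost with the covariates, where the ribosomal mean was 0.063 (adjusted p = 0.196) and the giant cell mean kept its size at −0.22 (adjusted p = 0.0715).

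Some marker genes differed far more between libraries of a group than between the groups. Yolk sac endoderm genes had a mean log2 fold change of 1.53 over 18 genes that did not pass (camera adjusted p = 0.671). The list score was −0.17 ± 0.88 in control and 0.13 ± 2.76 in AP libraries (SD, n = 4 and 5, exact permutation test, 2-sided p = 0.802). Afp, the fetal albumin-like protein of the yolk sac, was at 962, 2840, 3663 and 5934 CPM in the controls and at 24403, 664, 81.6, 25299 and 5836 CPM in AP replicates 1 to 5; it was singled out after its values were seen. Alb had a log2 fold change of 2.60 (edgeR adjusted p = 0.416) and Rbp4 one of 1.74 (adjusted p = 0.114). Rbp4 alone of this list was called by DESeq2 (higher, adjusted p = 0.00391), and it is a marked call in the authors' deposited table. Decidual stroma genes had a mean of 0.74 over 14 genes and did not pass (camera adjusted p = 0.344), with Des at 1.43 (edgeR adjusted p = 0.447). Both results depended on single libraries, since camera called yolk sac genes higher without AP replicate 3 (adjusted p = 0.00717) and decidual genes higher without AP replicate 4 (adjusted p = 0.00168). Across the libraries, the first principal component held 46.6% of the variance and did not separate the groups (exact permutation test, 2-sided p = 0.968, n = 4 and 5). The second held 18.6% (exact permutation p = 0.0397, n = 4 and 5).

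**Figure D4:**
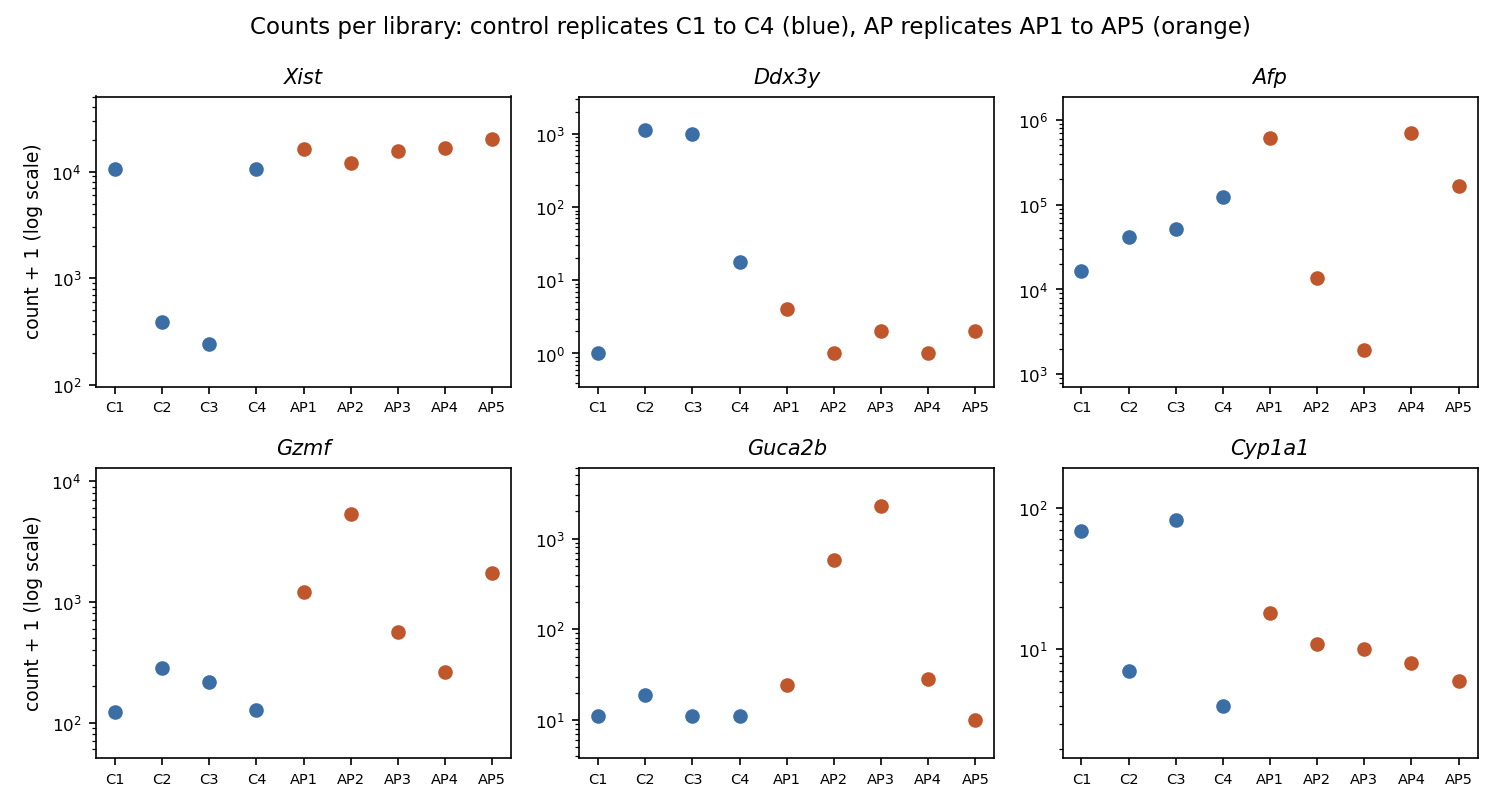
Counts plus 1 on a log axis for 6 genes in each of the 9 libraries, controls in blue (C1 to C4) and AP in orange (AP1 to AP5). Control replicates 2 and 3 have low Xist and high Ddx3y, AP replicates 1 and 4 have the highest Afp, and AP replicates 2 and 3 the highest Guca2b.

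The study also asked about placental nutrient transporters and DNA hydroxymethylation. The main glucose transporter gene Slc2a1 was at 1610 ± 47.1 CPM in control and 1454 ± 309 CPM in AP libraries (log2 fold change −0.15 ± 0.15 SE, edgeR adjusted p = 0.682). Slc2a3 had a value of 0.37 ± 0.14 (adjusted p = 0.302), the amino acid transporter gene Slc38a2 one of 0.11 ± 0.12 (0.714) and Slc38a4 one of −0.38 (0.408). No member of the glucose transport and glycolysis list (23 tested) or the amino acid transporter list (20 tested) passed, and camera called neither (adjusted p = 0.479 and 0.694). Of 20 tested genes of DNA methylation and hydroxymethylation, none passed, and camera did not call the list (adjusted p = 0.999). Tet1, which oxidises 5-methylcytosine, had a log2 fold change of 0.71 ± 0.21 (adjusted p = 0.212) at 1.35 ± 0.30 CPM in control and 2.21 ± 0.34 CPM in AP libraries. Tet2 (−0.06 ± 0.10), Tet3 (0.01 ± 0.11), Dnmt1 (−0.01 ± 0.11), Dnmt3a (−0.05 ± 0.08) and Dnmt3b (−0.15 ± 0.14) had adjusted p-values between 0.660 and 0.972. Cyp1a1, induced through the aryl hydrocarbon receptor by aromatic hydrocarbons, had counts of 67, 6, 81 and 3 in the controls and 17, 10, 9, 7 and 5 in the AP libraries, a log2 fold change of −2.67 ± 0.88 that did not pass edgeR's test (adjusted p = 0.255). DESeq2 called it lower (adjusted p = 0.0364), and it is a marked call in the authors' deposited table (0.0368). Cyp1b1 had a value of −0.78 ± 0.43 (0.458) and the receptor gene Ahr one of 0.81 (0.109), which DESeq2 called higher (adjusted p = 0.00576). Its list of 12 tested genes was not called (camera adjusted p = 0.671), though 2 passed adjusted over the list alone. DESeq2 called 2 members higher, Ahr itself and Rbp4, and 1 lower, Cyp1a1. Rbp4 is also a member of the yolk sac list.

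Camera called no other fixed list, while fry called the circadian clock list lower (adjusted p = 0.0481). No member passed edgeR's test over all genes in the lists of NF-kB, cytokines and chemokines (24 tested, camera adjusted p = 0.999; Nfkbia −0.40), interferon-stimulated genes (25, 0.306), unfolded protein and integrated stress response (22, 0.671), fatty acid and cholesterol handling (27, 0.955; Plin2 0.42), angiogenesis and hypoxia response (28, 0.999; Edn1 −0.65), prolactin family (22, 0.395), pregnancy-specific glycoproteins (20, 0.671), nuclear oxidative phosphorylation (32, 0.344), proliferation (25, 0.0876; Ccnd1 −0.64), heat shock proteins (17, 0.646; Hspa8 0.27) and extracellular matrix (28, 0.344). DESeq2, with 409 calls against edgeR's 50, called Nfkbia (adjusted p = 0.0320), Plin2 (0.0242), Edn1 (0.00361), Ccnd1 (0.000362) and Hspa8 (0.0101), 1 member of the unfolded protein list and 1 more of the angiogenesis list. The lists of imprinted genes (0.656), steroid hormone genes (0.999) and insulin, IGF and leptin signalling (0.479), each with 1 member called by edgeR, were not called by camera either. Among cell type lists, camera adjusted p-values were 0.460 for spongiotrophoblast and glycogen trophoblast (15 tested), 0.538 and 0.712 for syncytiotrophoblast layers I and II (7 each; DESeq2 called 1 in layer I), 0.990 for labyrinth progenitors (9), 0.0651 for fetal endothelium (15), 0.890 for mesenchyme and pericytes (13; DESeq2 called 1), 0.306 for smooth muscle (10), 0.646 for macrophages (15), 0.0651 for neutrophils (8; Ngp −1.51, DESeq2 adjusted p = 0.0316) and 0.999 for uterine epithelium (8). In 10 of the uncalled lists the mean, the median and the test differed in sign. B lymphocytes and the sex chromosome list had 1 tested gene each, and the mitochondrial genome list had 0 in the table.

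Sex chromosome transcripts differed between libraries that share the label female, which does not say whether it describes the mother or the placenta. Control replicates 2 and 3 held 1144 and 1004 counts of the Y-linked gene Ddx3y, while control replicates 1 and 4 held 0 and 17 and the AP libraries at most 3. Eif2s3y, Kdm5d and Uty followed the same split. Xist, the RNA of the inactive X chromosome, had 385 and 239 counts in control replicates 2 and 3 and between 10593 and 20282 in each of the other 7 libraries. Without control replicates 2 and 3, 11 genes were called, all lower and all among the 50, and 6 of them were immediate early genes, whose list then had a median log2 fold change of −0.72.

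The authors' deposited table compared the same groups over 13515 genes and held 398 genes with an adjusted p below 0.05, 158 higher and 240 lower. It marked 52 of them as calls, 29 higher and 23 lower, each with a change over 2-fold. All 50 genes called by edgeR were among the 398 and had the same sign. Over 13504 genes in both, log2 fold changes had the same sign in 97.4% (Spearman rho 0.99996 across genes, which are not independent replicates). DESeq2 run on the counts gave 409 calls and included all 398, with a median absolute difference in log2 fold change of 3.55e-06 from the authors' deposited table. A DESeq2 call and a marked call in that table are therefore 1 result on the same counts, not separate evidence. Of the 52 marked calls, 10 passed in edgeR (2 higher and 8 lower), 35 did not, and 7 were removed by the count filter. Each of the 7 had over 95% of its summed CPM in 2 libraries, so removal does not mean a low count in every library. The 5 highest fold changes in the authors' deposited table were those of Kap (log2 7.77), Sult1d1 (6.35), Cuzd1 (5.70), Guca2b (5.09) and Prap1 (4.88). In each of these, AP replicates 2 and 3 together held over 95% of the summed CPM. Guca2b and Prap1 did not pass in edgeR, and the other 3 were removed by its count filter. The 4 lowest, Eif2s3y (−10.61), Ddx3y (−9.90), Uty (−8.11) and Kdm5d (−7.58), were Y-linked genes with counts from control replicates 2 and 3. These 9 genes were singled out after their values were seen.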

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

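Single libraries were compared with the rest of their group over 216 groups of values, and 7 stood far from the others. Chance gives about 1 in 20, and some groups of values share genes. The 7 are no excess over chance, and no explanation was weighed. In control replicate 4, Fos was at 132 CPM against 89.2 CPM in the nearest control, and Cyp11a1 at 67.2 CPM against 82.1 CPM. In AP replicate 2, Gzmf was at 263 CPM against 60.8 CPM in the nearest AP library, and Gzmd at 219 CPM against 50.5 CPM. Ngp was at 1.29 CPM in AP replicate 4 against 0.764 CPM. The score of the DNA methylation and hydroxymethylation list was 0.059 in control replicate 3 against −0.037 in the nearest control. The score of mesenchyme and pericytes was −0.27 in control replicate 1 against −0.011.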

How the results depend on the processing

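The settings that left out pairs of libraries or Rn45s, thinned the counts or added tissue scores were chosen after seeing the data. All 50 called genes kept their sign in all 26 other settings. For the settings that only left out libraries this is no check, because the groups did not overlap in any of the 50. The median log2 fold change of the immediate early genes lay between −0.76 and −0.54, and at least 3 were called lower in each setting. The number of calls was less stable. Against 50 calls (14 higher, 36 lower), library size alone gave 23 (6 and 17), no low-count filter 8 higher, limma voom 9 higher, DESeq2 409 (162 and 247) and 1 surrogate variable 148 (70 and 78). DESeq2 and the surrogate variable included all 50. On simulated data DESeq2 recovered more changed genes than edgeR (78% against 72% of those changed by 1 on the log2 scale). It also made more false calls there (40 against 9). The cause of the larger numbers of calls was not tested. Leaving out 1 library gave 10 to 32 calls, 0 to 10 higher and 10 to 26 lower. Leaving out control replicates 2 and 3 gave 11 (0 and 11), AP replicates 2 and 3 gave 12 (2 and 10) and AP replicates 1 and 4 gave 21 (5 and 16), each with fewer samples. With the yolk sac and decidua scores as covariates 50 genes were called, 21 higher and 29 lower, of which 31 were shared. The split moved from 72% to 60.4% lower with DESeq2, 52.7% with the surrogate variable and 58% with the covariates.

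Replicate numbers 1 to 4 occur in both groups, and the labels do not say that they pair animals. Deviations of same-numbered libraries correlated at −0.45, 0.25, −0.03 and 0.63, so the numbers were not taken as pairs; only control replicates 2 and 4 matched their own number best. With the replicate number as a block over these 8 libraries, 3 genes were called, 0 higher and 3 lower.

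Among the lists, 7 calls became 1 with an estimated correlation. Fry made 4 calls, of which 3 were among the 7 (immediate early, histone and NRF2 genes) and 1 was the circadian clock. The number was 6 to 11 with 1 library left out, and 12 without AP replicates 2 and 3. Adjusted p-values under the settings other than estimated correlation and fry reached at most 1.50e-15 for immediate early genes and 0.0367 for NRF2 genes. They reached 0.0646 for histones (mean −0.29 without control replicates 2 and 3), 0.0740 for erythroid, 0.0890 for lymphocyte, 0.116 for giant cell and 0.931 for ribosomal genes. Yolk sac genes reversed to a mean of −0.45 without AP replicates 1 and 4, a call (adjusted p = 0.00375), and to −0.11 with the covariates (adjusted p = 0.0811). They were called higher without AP replicate 3 (1.84, adjusted p = 0.00717) and without AP replicates 2 and 3 (2.20). Decidual genes were called higher without AP replicate 4 (0.89, adjusted p = 0.00168), without AP replicates 1 and 4 (0.93) and with the replicate block (0.41, adjusted p = 0.0448), and reversed to −0.081 with the covariates. The covariates hold the scores of both lists. The agreement with the authors' deposited table moved from 50 shared calls to 398 with DESeq2. A smaller pseudocount left 5 list scores with an exact permutation p below 0.05, in place of 7.

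Genes near 0 reversed without passing in any setting. Slc38a2 was at −0.015 without control replicates 2 and 3 and −0.014 without AP replicates 2 and 3. With library size alone, Tet2 was at 0.017, Dnmt1 at 0.072 and Dnmt3a at 0.020. With the covariates, Tet2 was at 0.0067, Tet3 at −0.0019, Dnmt3a at 0.010 and Dnmt3b at 9.5e-05. Tet3 was at −0.0021 with upper-quartile factors and −0.11 without AP replicates 1 and 4. Dnmt1 was at 0.060 without control replicates 2 and 3 and 0.062 without AP replicates 1 and 4. With 1 library left out Tet3 ran from −0.059 to 0.11 and Dnmt1 from −0.10 to 0.058. The cause was not tested. Of 33 called genes followed one by one, 10 passed in all 9 fits that left out 1 library. The controls of Cyp1a1 spread from 3 to 81 counts. Thinning all libraries to the shallowest total left 46 calls.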

Other observations

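The tests below other than the counts over splits of the libraries were chosen after the results were seen. A group of genes was put together after the called genes were seen, so its counts are no test of enrichment. Of 17 dual-specificity phosphatase, Sprouty and Spred genes, 16 were tested, 4 fell and none rose in edgeR's test. Dusp1 and Spry4 were joined by Dusp8 (39.4 ± 3.89 to 24.4 ± 2.22 CPM, log2 fold change −0.69, edgeR adjusted p = 0.0180) and Dusp5 (42.8 ± 4.27 to 26.3 ± 3.52 CPM, −0.70, adjusted p = 0.0398). The other 12 did not pass and had a median log2 fold change of −0.21, with 8 below 0. Dusp8 passed in 4 and Dusp5 in 1 of the 9 fits that left out 1 library.

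Other called genes lay outside the naming rule and the fixed lists. Csrnp1, a nuclear protein gene, fell from 142 ± 14.4 to 82.5 ± 1.90 CPM (log2 fold change −0.79, edgeR adjusted p = 0.00178), and the GTPase gene Gimap6 from 19.6 ± 1.90 to 10.5 ± 0.29 CPM (−0.90, adjusted p = 0.00211). Both passed in all 9 fits that left out 1 library. Cirbp, a cold-inducible RNA-binding protein gene, fell by 0.75 on the log2 scale (adjusted p = 0.0180), and the hormone gene Stc1 by 0.86 (adjusted p = 0.0414). The splicing factor gene Rbm5 rose from 51.9 ± 2.47 to 73.9 ± 3.98 CPM (0.51, adjusted p = 0.0129). Rbm5 passed in 6, Cirbp in 3 and Stc1 in 0 of these 9 fits.

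The 9 libraries can be split into 4 and 5 in 126 ways, and 100 were drawn at random with the real one included. Of these, 2 gave at least the real 50 calls, 2 at least the real 14 higher genes and 2 at least the real 36 lower genes. Chance is argued against at the 5% level for each count only if the placentas are independent. The labels do not say whether they shared litters. The highest other split gave 549 calls, 130 higher and 419 lower. It set control replicate 4 and AP replicates 1, 4 and 5 against the rest, and points to a structure of the samples that crosses the groups. Those 4 libraries also had the highest yolk sac scores (0.827, 2.69, 2.50 and 0.835, against at most −0.071 in the others). Whether this accounts for the 549 calls was not tested. Chance cannot be excluded for the 7 called lists, since 82 of the 100 splits gave at least 7 and the highest other gave 19. For the 9 immediate early genes called lower, 1 split, the real one, gave as many, and the highest other gave 0.

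The first pattern is the lower level of immediate early genes in AP placentas. The median log2 fold change of the list was −0.68 after all libraries were thinned to 1 depth. This cannot speak for or against deeper sequencing of the AP libraries, because random thinning leaves the expected CPM ratio unchanged. Different shares of yolk sac and decidua are argued against as the whole cause, since the median was −0.76 with both scores as covariates. Handling or time of tissue collection that differed between the groups may also act on these genes, which respond within minutes. The score's gap of 0.54 between the lowest control and the highest AP library cannot be told apart from such a difference, because no collection label varies within a group, and an effect of the exposure stays open as well.

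The second pattern is the spread of yolk sac genes over the AP libraries, with Afp 309-fold higher in the highest than in the lowest AP library. Exposure raising or lowering yolk sac genes in every AP library is argued against, since 3 AP scores lay above the control range and 2 below it. Yolk sac tissue in some of the sampled pieces may account for it. The median SD of log2(gene/Afp) over the 9 libraries was 0.55 for 17 other genes of the list, against a median SD of 2.27 for the genes themselves, a ratio of 0.242 where 0.25 was the bound set. Rbp4 was an exception, with a ratio SD of 2.27.

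The third pattern is the Y-linked genes that lead the lower genes of the authors' deposited table. Lower expression of Y-linked genes in exposed placentas is argued against, since 2 control libraries had at most 20 counts of Ddx3y. A Y chromosome in 2 control libraries is a candidate explanation. All 4 of Ddx3y, Eif2s3y, Kdm5d and Uty had at least 100 counts in control replicates 2 and 3 alone and at most 20 in each of the other 7 libraries, and Xist was lowest in those 2. Sex of the fetus is then unevenly spread over the groups, and its effect on other genes was not tested apart from the fit without these 2 libraries. In that fit 11 of the 50 called genes were called. All 50 kept their sign, but this is no check, because their groups did not overlap before the libraries were left out. The histone list moved from a mean of −0.51 to −0.29 and lost its call (camera adjusted p = 0.0646).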
